A study of Zea mays with 6 samples.

How the data were processed

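Per the labels' protocols, total RNA was taken with Trizol from maize endosperm at 12 days after pollination and made into Illumina libraries; how messenger RNA was selected is not given in the sources used here. The series holds 6 libraries, 3 from wild type (WT) and 3 from the mutant smk8-ref. Per the submitters' processing notes the tools were HISAT, a spliced read aligner, and StringTie, which assembles and quantifies transcripts. Their versions, roles and settings, and the genome build, are not given in the sources used here; contig names in the deposited table begin with B73V4, the prefix of an assembly of the inbred line B73, and coordinates below are those of the table.

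The authors deposited 1 table of 86771 transcripts with an FPKM value (fragments per kilobase of transcript, scaled to the sequenced total) for each library. Every transcript in the table is marked as protein-coding. The same deposited table holds the authors' own comparison of the genotypes as a linear fold change (a ratio), a log2 fold change, a p-value and a q-value per transcript, and a mark of up, down or no change. The model behind that comparison is not stated in the sources used here, and the values are quoted only as the authors' deposited table.

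Gene identity limits what can be named. Transcript FPKM values were summed by the locus identifier that precedes the transcript number, which gave 36781 genes. The table pairs 237 of these genes with one of 201 distinct names, and leaves the others with an identifier alone. The RefSeq gene table used here (assembly Zm-B73-REFERENCE-NAM-5.0) matched 0 of the identifiers, so no further names were given. Several names stand for more than 1 gene (the histone names H4C7 and H3C2, for example), and such genes are told apart by identifier.

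Depth could not be read from the files as read totals. The FPKM values of each library summed to between 287260 and 321002. Among genes with 1 transcript and a value below 0.15 in smk8-ref replicate 1, the most frequent log2 ratio to another library, at 3 decimals, gave the relative worth of 1 read, and from it depths of 1.18 (WT replicate 1), 0.930 (WT replicate 2), 1.05 (WT replicate 3), 0.954 (smk8-ref replicate 2) and 0.848 (smk8-ref replicate 3) relative to smk8-ref replicate 1. At most 0.429% of the pairs lay at that ratio, so these relative depths are uncertain and whole reads were not recovered. No count test was therefore run, and no counting interval is given. StringTie divides reads among overlapping transcripts and similar copies, and a gene can be listed at 0 in 1 library and at a high level in another of the same genotype. No statement of presence or absence was therefore drawn from a 0.

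Genes with FPKM of at least 1 in at least 3 of the 6 libraries were tested (15858 genes). The genotypes were compared on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a variance trend over expression, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). A fold change is on this scale, with a pseudocount of 1, which understates the change of genes with low values. All adjusted p-values of single genes are from this fit. Gene lists were tested with camera from limma with a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The series text calls the libraries biological repeats but does not say whether they come from separate ears or plants, so the p-values measure the spread between these libraries.

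The design, the rule for naming genes, 28 gene lists and the alternatives were fixed before the data were examined. The lists were written as name and description patterns, and the description column of the table is blank, so they could match by name alone. With at least 5 measured members, 3 lists were tested (core histones, cytosolic ribosomal proteins, photosynthesis). A further 7 lists had 1 to 4 measured members, which are given as single genes, and 18 had none. The rule named, among genes past the threshold with a name, non-overlapping groups and a mean of at least 5 FPKM in the higher group, the 8 largest rises and the 8 largest falls, the 2 largest rises and falls within each list, and the 2 largest rises and falls among genes without a name. It also asked for o2, pbf1, wx1, sh2, bt2, sh1, mn1 and the most abundant zein, which were not analysed by name here. These genes can still be among the tested genes that have an identifier alone. Since 27 named genes passed the threshold in all, others among them were also named, after their values were seen, as were named genes below the threshold. Some members of the ribosomal protein list are not reported here by name. Groups by chromosome (plastid, mitochondrion), the aquaporins, the nuclear ribosomal proteins, and a group of embryo, meristem and oil-body genes were defined after the names in the table had been seen.

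The procedure was tested on simulated data for the same comparison, with values for the 15858 genes drawn from the fitted means and spreads and 200 genes changed. Genes were drawn independently of one another. The changed genes all had a mean log2(FPKM + 1) above 2, so recovery at lower levels was not measured. Of 100 genes changed by 1 on the log2 scale 52% were recovered, and of 100 changed by 2 93% were. Of the calls, 7.05% were false, and none of the changed genes was called in the wrong direction. With 1 WT library left out, 24% and 92% were recovered.

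Replicate numbers are shared by the genotypes. After removal of the genotype means, same-numbered libraries correlated across genes at 0.01, -0.01 and 0.08. These low values gave no ground for a block in the main fit, but so few pairs cannot exclude pairing by number. The choice matters: 36 genes passed with the replicate number as a block, against 1205 without it. The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, scaling by TMM factors (trimmed means of log ratios, trimming 30% of log ratios and 5% of levels), by medians of ratios or to a common sum (TPM), quantile normalization, a replicate block, no variance trend, transcripts in place of genes, and each library left out in turn. Summing by name and adding the covariate of the authors' model were chosen after seeing the data.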

Results

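Messenger RNA of maize endosperm was profiled by RNA sequencing at 12 days after pollination in 3 WT and 3 smk8-ref libraries. smk8-ref is the reference allele of a maize mutant, and the endosperm is the tissue of the kernel that stores starch and protein. The comparison asks which genes differ in the endosperm between mutant and WT. FPKM values summed to between 294002 and 305360 in smk8-ref and between 287260 and 321002 in WT, and the number of genes at 1 FPKM or more was 15625, 15988 and 15942 in smk8-ref replicates 1 to 3 and 14350, 14920 and 15312 in WT replicates 1 to 3. The 10 most abundant transcripts held 14.9%, 12.8% and 11.4% of the FPKM sum in the smk8-ref libraries and 10.7%, 9.82% and 9.09% in the WT libraries. The labels do not identify the gene affected in smk8-ref, so its own level was not analysed here.

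The genotypes separated on the first principal component, which held 44.4% of the variance of log2(FPKM + 1) and placed the smk8-ref libraries at 39.9, 30.6 and 27.8 and the WT libraries at -44.6, -33.9 and -19.8. WT replicate 3 lay nearest to smk8-ref on this component, and also stood apart on the second component, at -45.4. Pearson correlations across genes were 0.937 to 0.953 within genotypes and 0.897 to 0.930 between them. Genes are not independent replicates, so these correlations carry no p-value.

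Among named genes past the threshold, the largest falls in smk8-ref endosperm were those of GAPC3 and PHI1, which encode enzymes of glycolysis. Of the measured members, 8 of 19 core histone genes and 6 of 25 ribosomal protein genes fell and none rose; neither list passed with an estimated correlation (adjusted p = 0.30 and 0.13 with an estimated correlation). HMT-1, a homocysteine methyltransferase gene, and LON1, a protease gene, were higher. Of 15858 genes tested, 1205 (7.60%) passed an adjusted p of 0.05 in limma, 538 higher and 667 lower in smk8-ref. A change of at least 2-fold was found for 465 of them, 268 higher and 197 lower. The balance of directions depended on the libraries and the scale: 885 genes were higher and 540 lower without WT replicate 3 (526 and 199 with a 2-fold change), 144 and 356 without WT replicate 2 (125 and 188), and with a pseudocount of 5 the 2-fold changes were 102 higher and 107 lower. All 1205 had non-overlapping groups, as did 34.5% of all tested genes. Random labels would give 10% on average, but genes are not independent replicates, so the difference carries no p-value. Of the 27 named genes past the threshold, 25 were lower and 2 were higher. Each of these lost its call in some of the 17 gene-level alternatives run, from 3 for PHI1, 5 for GAPC3, 6 for HMT-1 and 8 for LON1 to 12 for atpB and 13 for ycf73-A, and ESR3 lost its call in 11 of 16; none reversed. The number of calls rested on the full set of libraries: it was 38 without WT replicate 1, 500 without WT replicate 2, 38 without smk8-ref replicate 1, 28 without smk8-ref replicate 2 and 214 without smk8-ref replicate 3. Without WT replicate 3 it was 1425, and the number with a 2-fold change was 725. All 1205 genes kept their direction in these fits, but with non-overlapping groups no direction can reverse when 1 library is left out.

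GAPC3 and PHI1 both fell by more than 2-fold. GAPC3 (Zm00001d051001, chromosome 4, 136187079 to 136190530), a cytosolic glyceraldehyde-3-phosphate dehydrogenase, fell from 2088 ± 195 FPKM (SD, n = 3) in WT to 526 ± 191 in smk8-ref, a log2 change of -2.04 ± 0.26 (SE, adjusted p = 0.019). PHI1 (Zm00001d034256, chromosome 1), a glucose-6-phosphate isomerase, fell from 176 ± 16.6 to 51.9 ± 10.4 FPKM, a log2 change of -1.76 ± 0.17 (adjusted p = 0.014). GAPC2, a second gene of the same enzyme as GAPC3, stood at 453 ± 83.2 FPKM in WT and 404 ± 26.6 in smk8-ref and did not pass (log2 change -0.15, adjusted p = 0.60). PPDK2, a pyruvate phosphate dikinase and the single measured member of the fixed list of glycolysis and pyruvate metabolism, stood at 2648 ± 343 FPKM in WT and 1795 ± 285 in smk8-ref and did not pass (adjusted p = 0.14).

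Of 19 measured core histone genes, named H4C7 (histone H4) or H3C2 (histone H3), 8 fell, none rose and 11 did not pass; 13 fell when adjusted over the list alone. The list passed camera with the preset correlation (adjusted p = 1.1e-06 over 3 lists), and neither camera with an estimated one (adjusted p = 0.30 with an estimated correlation) nor fry (adjusted p = 0.065). Their median log2 change was -0.87, against 0.05 for all genes. The largest falls were those of H4C7 at Zm00001d010575, from 81.9 ± 28.2 to 28.8 ± 2.98 FPKM (adjusted p = 0.027), and H4C7 at Zm00001d039733, from 146 ± 38.4 to 53.3 ± 12.4 FPKM (adjusted p = 0.028). H3C2 at Zm00001d045268 fell from 72.0 ± 17.5 to 27.0 ± 3.29 FPKM (adjusted p = 0.020). The other H4C7 and H3C2 genes past the threshold, Zm00001d020585, Zm00001d051478, Zm00001d008669, Zm00001d036250 and Zm00001d021477, fell by log2 changes between 0.68 and 1.19. PCNA, the sliding clamp of DNA replication, stood at 32.4 ± 6.06 FPKM in WT and 15.7 ± 5.35 in smk8-ref, just above the threshold (adjusted p = 0.051), and CDC2, a cyclin-dependent kinase, stood at 12.5 ± 2.67 and 12.0 ± 0.943 (adjusted p = 0.90). Without WT replicate 3, which had the highest level of many histone genes, 4 fell and 1 rose, and without any other single library 0 to 7 fell. Histone genes of one class are near-identical, so the division of reads among them is uncertain.

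The fixed list of cytosolic ribosomal proteins had 25 measured members, of which 6 fell, none rose and 19 did not pass; 11 fell when adjusted over the list alone. The list passed camera with the preset correlation (adjusted p = 1.9e-06) and fry (adjusted p = 0.015), and not camera with an estimated one (adjusted p = 0.13 with an estimated correlation). It failed fry without WT replicate 1 (adjusted p = 0.13), without smk8-ref replicate 1 (adjusted p = 0.065) and with the covariate of the authors' model (adjusted p = 0.18). Under the other alternatives it passed fry. RPL29 fell from 21.9 ± 2.93 to 11.3 ± 2.44 FPKM (adjusted p = 0.037), and RPL39 at Zm00001d045121 from 71.0 ± 18.8 to 37.0 ± 3.62 FPKM (adjusted p = 0.047). RPS4 fell from 184 ± 20.7 to 117 ± 12.9 FPKM and RPL17 from 109 ± 14.4 to 70.5 ± 4.52 FPKM (adjusted p = 0.043 for both). The names matched 8 genes on the plastid chromosome, none of which passed. The 17 nuclear members had a median log2 change of -0.65 and held all 6 falls. As a group defined afterwards, these nuclear members did not pass fry (adjusted p = 0.090 over 5 groups, unadjusted p = 0.018). With single libraries left out, 0 to 4 members fell. On the plastid chromosome rps16 was listed at 0 in WT replicate 1 and at 238 and 265 FPKM in WT replicates 2 and 3.

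**Figure D1:**
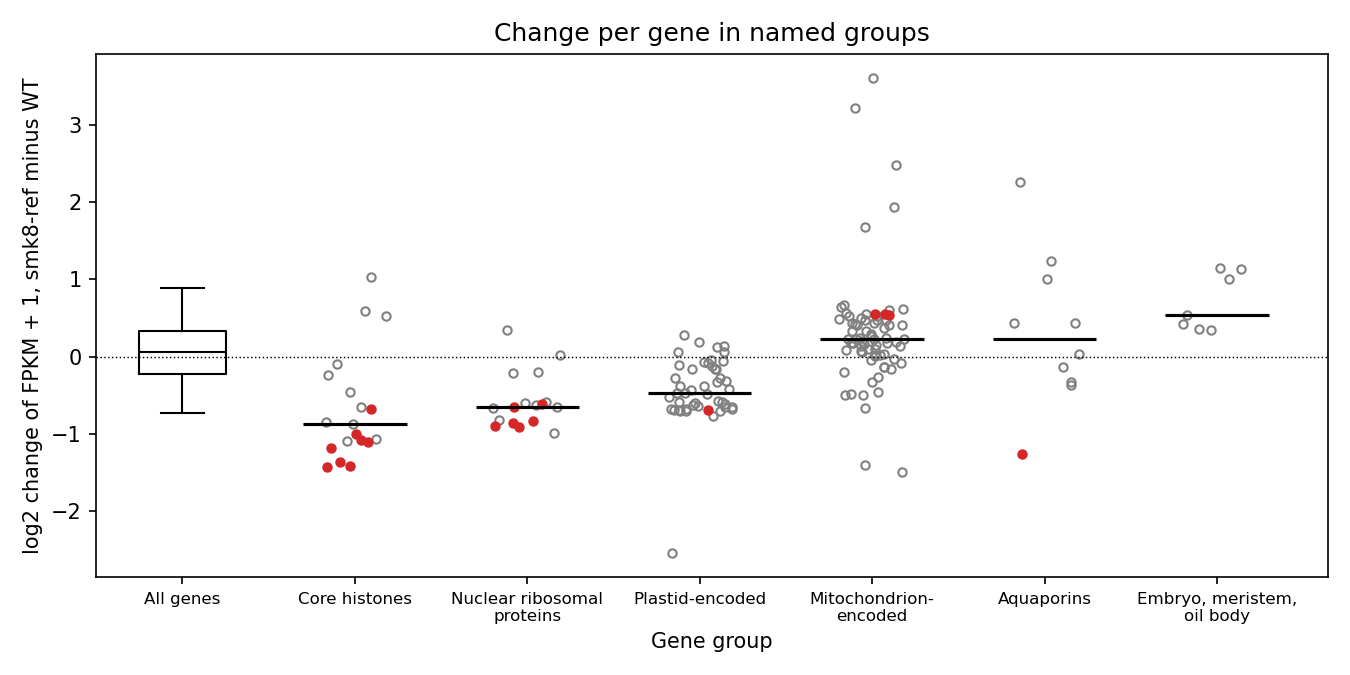
Log2 change of FPKM + 1, smk8-ref minus WT, per gene (vertical axis) for all genes (box: quartiles and median, whiskers: 5th and 95th percentiles) and for 6 named groups (points: genes; filled red: past the threshold; horizontal lines: group medians). The median lies at -0.87 for core histones and -0.65 for nuclear ribosomal proteins, against 0.05 for all genes.

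The photosynthesis list held 5 measured genes, psaC, psbB, psbC, psbH and psbA, and none passed the threshold. When adjusted over the list alone, 3 fell and 1 rose. The median log2 change was -0.60, and psbA, which the table places on an unplaced contig, was the one higher, at 173 ± 20.1 FPKM in smk8-ref and 133 ± 5.44 in WT (adjusted p = 0.12). The list stood at the threshold in camera (adjusted p = 0.049968), failed it with an estimated one (adjusted p = 0.38 with an estimated correlation) and failed it under most alternatives, among them TMM scaling (adjusted p = 0.071) and quantile normalization (adjusted p = 0.46).

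Further named genes also fell. The profilins PRO4 and PRO5, which bind actin monomers, fell from 204 ± 47.9 to 99.8 ± 10.5 FPKM (adjusted p = 0.037) and from 150 ± 14.3 to 85.0 ± 4.88 FPKM (adjusted p = 0.022). SIP2-1, an aquaporin of the small basic intrinsic protein class, fell from 26.8 ± 3.40 to 10.6 ± 1.01 FPKM (adjusted p = 0.015). DER1.2, a derlin of the endoplasmic reticulum, fell from 23.0 ± 1.81 to 12.8 ± 2.35 FPKM (adjusted p = 0.033). Its relative DER1.1 had a higher mean in smk8-ref, 15.8 ± 3.29 FPKM against 9.97 ± 1.90 in WT, and did not pass (adjusted p = 0.11). DER2.1 and DER2.2 had lower means in smk8-ref and did not pass (adjusted p = 0.28 and 0.22). The chaperonin CPN60II fell from 80.5 ± 2.26 to 48.7 ± 7.36 FPKM (adjusted p = 0.034), and EFTS, an organellar translation elongation factor, from 17.0 ± 1.56 to 10.1 ± 1.74 FPKM (adjusted p = 0.041). The gene named atpB at Zm00001d038929 on chromosome 6 fell from 126 ± 15.1 to 72.3 ± 15.8 FPKM (adjusted p = 0.044), and ycf73-A, a plastid reading frame, from 26.8 ± 3.30 to 16.3 ± 2.63 FPKM (adjusted p = 0.048). The other plastid copy of ycf73-A stood at 24.9 ± 2.52 and 15.3 ± 2.93 FPKM (adjusted p = 0.053).

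The 2 named genes that rose were HMT-1 and LON1. HMT-1 (Zm00001d048060, chromosome 9) rose from 5.98 ± 2.19 to 19.0 ± 2.28 FPKM, a log2 change of 1.57 ± 0.26 (adjusted p = 0.025). Its relatives HMT-2 (5.94 ± 2.48 FPKM in WT and 4.15 ± 0.805 in smk8-ref) and HMT-3 (26.1 ± 3.10 and 34.8 ± 1.93) did not pass. LON1, an ATP-dependent protease of the Lon type, rose from 19.2 ± 1.40 to 30.7 ± 2.63 FPKM, a log2 change of 0.65 ± 0.12 (adjusted p = 0.032).

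**Figure D2:**
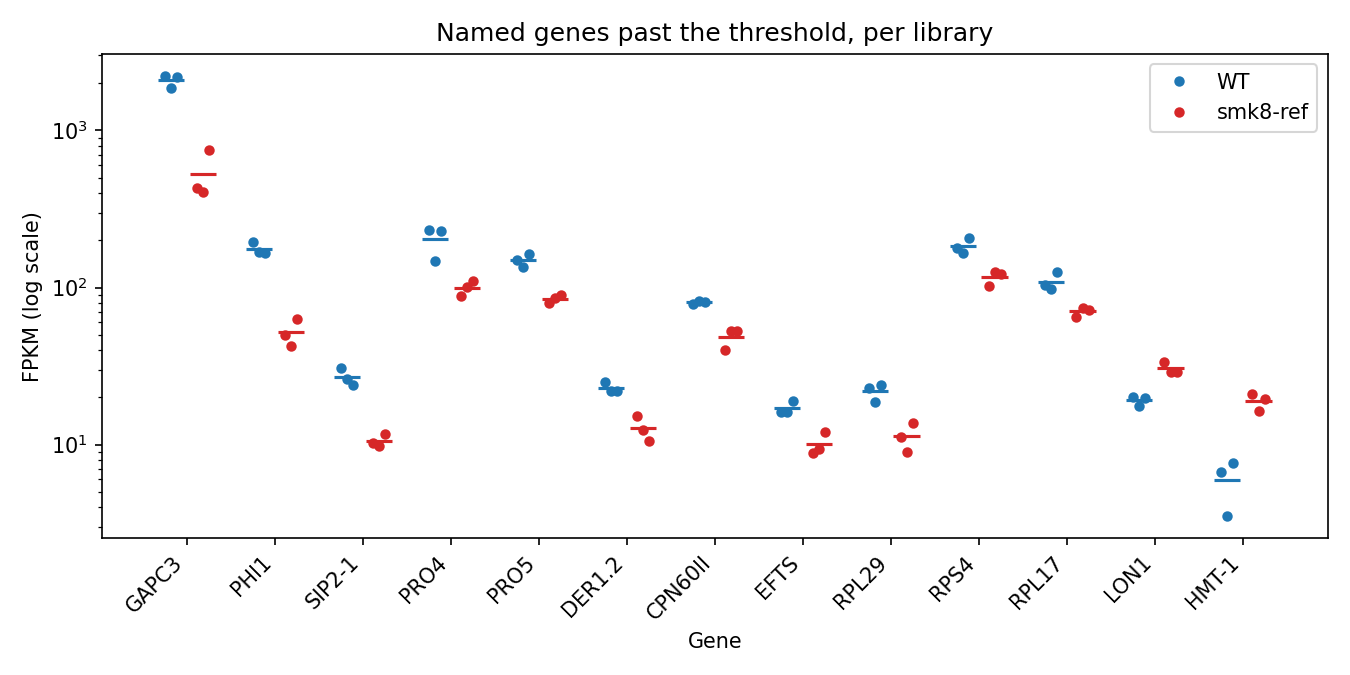
FPKM per library (points, log axis) for 13 named genes past the threshold in WT (blue) and smk8-ref (red), with horizontal lines at the group means of 3 libraries. Only HMT-1 and LON1 of these genes lie higher in smk8-ref, and no WT point overlaps a smk8-ref point of the same gene.

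Few markers of other kernel compartments were measured. ESR3, a gene of the embryo-surrounding region of the endosperm, fell from 3.71 ± 0.840 to 0.966 ± 0.730 FPKM (adjusted p = 0.043), while its neighbour ESR1 stood at 1.71 ± 0.202 and 2.81 ± 3.43 FPKM (adjusted p = 0.90) and the aleurone receptor kinase gene CR4 at 7.86 ± 0.927 and 9.80 ± 0.566 FPKM (adjusted p = 0.21). The imprinting-related genes FIE1 (27.0 ± 11.2 and 23.5 ± 6.62 FPKM) and FIE2 (2.97 ± 1.43 and 3.44 ± 0.292 FPKM) and the DNA methyltransferase gene DMT105 (11.7 ± 1.49 and 9.77 ± 1.49 FPKM) did not pass (adjusted p = 0.80, 0.62 and 0.37). The single measured members of the glutathione list, GST4 (1.09 ± 0.616 and 0.773 ± 0.636 FPKM), and of the hormone list, CISZOG1 (1.23 ± 0.177 and 1.59 ± 0.395 FPKM), did not pass, nor did either heat shock gene named HSP18 (adjusted p = 0.68 and 0.29). The oil-body gene OBAP2A stood at 15.2 ± 7.32 FPKM in WT and 33.1 ± 7.86 in smk8-ref (adjusted p = 0.077), and the meristem gene KN-1 at 0.621 ± 0.515 and 1.28 ± 0.274 (adjusted p = 0.24). The oil-body gene OBAP2B was at 3.06, 8.23 and 23.6 FPKM in WT replicates 1 to 3 and at 21.5, 16.2 and 24.7 FPKM in smk8-ref replicates 1 to 3, so that WT replicate 3 lay within the smk8-ref values. All 7 measured genes of the embryo, meristem and oil-body group had higher means in smk8-ref, and none passed in limma over all libraries, while 3 passed without WT replicate 3. Across all genes 4492 had an unadjusted p under 0.05.

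Among genes without a name, the largest rises were those of Zm00001d035680 (chromosome 6, 40863632 to 40864319) and Zm00001d011012 (chromosome 8). Zm00001d035680 rose from 11.3 ± 3.73 to 465 ± 161 FPKM, a log2 change of 5.22 ± 0.30 (adjusted p = 0.0020), and kept its call in all 17 gene-level alternatives run, as did Zm00001d051856, while Zm00001d011012 and Zm00001d044874 each lost theirs in 4 of these. Zm00001d011012 rose from 2.0 ± 1.1 to 47.3 ± 26.9 FPKM (adjusted p = 0.016). The largest falls were those of Zm00001d051856 (chromosome 4), from 88.2 ± 31.9 to 3.82 ± 1.45 FPKM (adjusted p = 0.0070), and Zm00001d044874 (chromosome 9), from 92.4 ± 25.3 to 7.29 ± 4.33 FPKM (adjusted p = 0.019).

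The authors' deposited table marks 2197 transcripts as up and 2006 as down. In the authors' deposited table every marked transcript has an absolute log2 fold change above 1 and every other one below 1, and p-values of marked transcripts reach 0.78, so the marks follow the fold change alone. The smallest q-value in the authors' deposited table is 0.40, and 5784 transcripts have a p-value under 0.05. Of the 538 genes higher in limma, 312 had a transcript marked up in the authors' deposited table and 15 had one marked down. Of the 667 genes lower in limma, 299 had a transcript marked down there and 24 had one marked up.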

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

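Summing by name and adding the covariate of the authors' model were chosen after the data were seen, and the other alternatives were fixed before the data were examined. All 1205 genes past the threshold kept their direction under every alternative fitted to the same genes. With 1 library left out, another pseudocount or the replicate block, their non-overlapping groups fixed this in advance. The count stayed between 1019 and 1495 with pseudocounts of 0.1 and 5, a filter at 5 FPKM, TMM, median-of-ratios and TPM scaling, no variance trend and summing by name. It was 388 (279 with a 2-fold change) with no filter, where 36781 genes were tested, 779 with quantile normalization, 490 among transcripts and 6 (6 with a 2-fold change) with the covariate of the authors' model. With a pseudocount of 5, 209 genes had a 2-fold change. With 1 library left out the count ranged from 28 to 1425 and the count with a 2-fold change from 28 to 725. On simulated data leaving out 1 WT library lowered the calls from 156 to 124. There genes were drawn independently and 200 were changed, so the simulation cannot say how many calls the real data should lose. TMM scaling gave 540 higher and 955 lower. With the replicate number as a block, 36 genes passed, all 36 with a 2-fold change, and 36 of them were among the 1205; only replicate 3 correlated best with its own number. The photosynthesis list had a median log2 change of -0.60 and lost its call with a pseudocount of 0.1 (-0.62), no filter (0.0016), a filter at 5 FPKM (-0.60), TMM (-0.64), median-of-ratios (-0.64), TPM (-0.57) and quantile scaling (-0.48), the replicate block (-0.60), transcripts (-0.60) and the authors' covariate (-0.66); with 1 library left out it ranged from -0.75 to -0.49, and the call was lost without WT replicates 1 and 2 and without smk8-ref replicates 1 and 2 (adjusted p = 0.059, 0.14, 0.052 and 0.14). Core histones and cytosolic ribosomal proteins kept their calls in camera with the preset correlation under all alternatives that gave a value, and summing by name left too few histone names for a test. Their called members were fewer in several: 0 in both lists with the replicate block and with the authors' covariate, 3 histones and 0 ribosomal proteins with no filter, 1 and 0 among transcripts, and 5 and 1 with quantile normalization, where the ribosomal median was -0.25. Of 3 lists, 0 passed with an estimated correlation and 1 with fry. In the authors' deposited table, 4203 marked transcripts became 0 at a q-value under 0.05, and 0 with a 2-fold change as well. The cause of these losses was not tested. The mitochondrial group lost its call with no filter (0.05), without WT replicate 3 (0.20) and with the authors' covariate (0.05), the plastid group with quantile normalization (-0.11), and the embryo, meristem and oil-body group with the authors' covariate (0.26). For single called genes, some unnamed, 280 alternative values passed, 246 did not, and 0 reversed. Count tests with edgeR and DESeq2 were not run, since the table gives no counts and whole reads were not recovered, and absolute depth is unknown.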

Other observations

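The gene groups here were defined after the names in the table were seen, and the tests of the embryo, WT replicate 3, covariate and chromosome 4 patterns, with their bounds, were chosen after the results were seen. Genes on the mitochondrial chromosome held 8.04 ± 0.340% of the FPKM sum in smk8-ref and 6.03 ± 0.689% in WT (SD, n = 3; two-sided exact permutation p = 0.1, the smallest this design allows). Of 72 measured mitochondrial genes, 3 rose, none fell and 69 did not pass in limma, and 56 had a positive log2 change (median 0.23, camera adjusted p = 0.011 over 5 groups, adjusted p = 0.52 with an estimated correlation). Without WT replicate 3, 3 of these genes rose, and 5 with quantile normalization. The count of rises was 0 without any other single library and with the replicate block. It was also 0 with no filter, among transcripts and with the covariate of the authors' model, and 1 with no variance trend. A fall of 1 gene was called with a pseudocount of 5, a filter at 5 FPKM, TMM scaling and median-of-ratios scaling. Genes on the plastid chromosome held 1.52 ± 0.291% in smk8-ref and 1.74 ± 0.341% in WT (exact permutation p = 0.5). Of 47 measured plastid genes, 1 fell and none rose, and 41 had a negative log2 change (median -0.47; camera adjusted p = 3.3e-07, adjusted p = 0.52 with an estimated correlation).

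Of 10 measured aquaporins, channel proteins for water and small solutes, 1 fell, SIP2-1, and none rose (median log2 change 0.23, camera adjusted p = 0.81), while 3 rose and 1 fell without WT replicate 3, and 1 rose and 1 fell with a pseudocount of 5. None passed without WT replicate 1, without smk8-ref replicate 1 or 2, with the replicate block or with the covariate of the authors' model. The tonoplast gene TIP3-1 stood at 8.63 ± 7.57 FPKM in WT and 38.3 ± 16.7 in smk8-ref (adjusted p = 0.064), and TIP1-1 at 16.7 ± 7.64 and 38.9 ± 9.29 (adjusted p = 0.068). The 17 nuclear ribosomal protein genes, as a group defined afterwards, passed camera with the preset correlation (adjusted p = 8.3e-07 over 5 groups), and neither camera with an estimated one (adjusted p = 0.52 with an estimated correlation) nor fry (adjusted p = 0.090). Among transcripts, 13 genes had 1 transcript that rose and another that fell, of 4361 genes with more than 1 transcript tested.

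The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 1205 genes, 465 of them with a 2-fold change, and the highest of the other splits called 3 and 3; 1 split, the real one, reached each count.

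Embryo, meristem and oil-body genes had higher means in smk8-ref, and WT replicate 3 was the highest WT library for all 7 measured members, within the range of smk8-ref for OBAP1A, OBAP2B, RS2 and LBD6. A larger share of embryo tissue in these libraries is a hypothesis. All 7 means went that way, and the list passed camera with the preset correlation (adjusted p = 0.011 over 5 groups). It passed neither camera with an estimated correlation (adjusted p = 0.52) nor fry (adjusted p = 0.14). Displacement of WT replicate 3 towards smk8-ref was tested across genes, which are not independent replicates, and correlated at 0.145 and 0.207 with the change of smk8-ref in the 2 arrangements of the other WT libraries. Of these values 0.207 passes the bound of 0.2 set for a shared axis, which both had to pass, and 0.145 does not, nor does either lie under the bound of 0.1 set against it, so tissue mix, developmental stage and genotype cannot be told apart.

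The authors' deposited table gives 26.5% of transcripts a log2 fold change opposite in sign to the difference of group means, and 340 (8.09%) of the marked ones. The summed log2 values below the upper quartile were taken as a library covariate. A fit of log2(FPKM + 1) on genotype and this covariate gave the authors' deposited log2 fold changes to within 6.3e-14. A model with this covariate thus accounts for the opposite signs. That covariate ran from 17069.5 to 19987 in WT and from 20599.4 to 22117.7 in smk8-ref, so it separates the genotypes, and adjusting for it left 6 genes past the threshold. Whether it follows technical variation or the genotype was not settled by these values.

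On chromosome 4, a run of 22 measured genes (5846538 to 6359146) held 10 genes past the threshold, all with a 2-fold change and 1 of them lower (log2 change -1.35), and 17 with higher means in smk8-ref. A window of 20 genes within it held 8 of the 2-fold calls, and random placement of the calls gave a window with 8 in 2 of 10000 placements (permutation p = 3e-04). This argues against chance placement of independent calls. Reads divided among similar copies can tie their calls together, so the p-value can overstate the evidence. Movement of reads among measured genes of the run with equal length would leave their summed FPKM alone. The FPKM summed over the run was 5219 ± 2369 in WT and 18352 ± 4954 in smk8-ref (log2 change 1.88 ± 0.44, SE, exact permutation p = 0.1, the smallest this design allows). Reads moved between genes of unlike length, from similar copies outside the run, or from copies below the filter would change that sum. Such movement stays open. A different haplotype linked to the mutation stays open: the 20 genes beside the run held 0 2-fold calls where 0.591 would be due, too few to decide. In the run, 13 genes of 399 to 804 bp with 1 transcript and a mean of at least 30 FPKM were all higher, and 8 of them passed. What the genes of the run encode was not analysed.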
